A study of Mus musculus with 14 samples.

How the data were processed

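RNA from the epididymal fat pad of 14 male mice was hybridised to Affymetrix whole-transcript arrays, with the groups, diet and replicate numbers taken from the labels, which call the replicates of a group biological. The authors deposited 1 table of log2 values per probe set and array, made with RMA per the submitters' processing notes; no version is named. RMA fits a background model, quantile normalizes the arrays and summarises the probes of a set on the log2 scale, so total brightness is made equal between arrays and a change shared by most genes would be removed. Its settings, whether all 14 arrays were processed together, and any filter are not given in the sources used here. The deposited values ran from 4.21 to 14.5, the range of log2 RMA output, which is the basis for reading them as log2. No value was rescaled or filtered for the main results, while some of the alternatives rescaled or filtered them.

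The table has 34760 rows. The platform annotation pairs 21640 of them with 1 gene symbol, 1321 with several and 11799 with none; rows of the latter kinds were not named. Of the rows with 1 symbol, 21553 matched a gene of the GRCm38.p6 reference table by Entrez ID, and 0 symbols changed. For the 954 genes with more than 1 probe set, the set with the highest mean over all arrays was kept, which left 19937 genes. Among named genes with several sets, the sets of Fabp5, Insr, Irs1, Prune2 and Trabd2b gave the same sign in the diet contrasts, except Insr in EKO. That reference was used only for names and for which genes neighbour each other, since the genome build of the array annotation is not given.

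Each comparison was a contrast in a model with 1 mean per group fitted to all 14 arrays (limma 3.58.1 in R 4.3.3; lmFit and eBayes with its default prior, 10 residual degrees of freedom). The contrasts were Western against normal diet in WT and in EKO, EKO against WT on each diet, and the difference between the diet effects. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no fold minimum. Gene lists, 33 in all with 562 of 608 members measured, were written from general knowledge of adipose tissue, diet and lipoprotein metabolism, and of other cell types and tissues that the dissected pad could hold. They were tested with camera at a preset correlation of 0.01 and adjusted over the 33 lists, with camera at an estimated correlation and fry as alternatives; the members past the threshold are counted over all genes and adjusted over the list alone. Correlations of effects across genes carry no p. Figures were drawn with matplotlib 3.10.9. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives that concern array background were added afterwards. The cutoffs on unadjusted p for the genes near Apoe were not among the fixed tests.

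Genes are named by a rule. Apoe and Lep are given in each comparison and Nnt in the genotype comparisons. In each pairwise comparison the 10 genes with the largest rise and the 10 with the largest fall are named among those that passed and whose groups did not overlap; where none passed in a direction, the 5 with the smallest p are given. For the interaction the 10 with the smallest p are named. In a list, up to 4 members are named, the highest and lowest pairs among those that passed, or the pair with the smallest p where none did. Predicted genes, small RNAs, chemosensory receptors and antigen receptor segments are passed over in naming but counted. The analysis was tested on simulated values with the means and spread of these genes: of 100 genes changed by 1 on the log2 scale, 83% were recovered for diet in WT (3 against 3 arrays) and 94% for diet in EKO (4 against 4), with 10 false calls each among 193 and 204 calls over 19937 genes. The simulated noise was independent between genes and held no structure shared by arrays, so these shares need not hold for the real arrays.

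The arrays were compared before any averaging, and arrays of the same group correlated at 0.976 to 0.995. The level of 1194 olfactory and vomeronasal receptor rows, most of which fat is not known to use, was taken as background. Where 1 group mean of a named gene lay at or below 6.85, the highest array mean of these rows, the change is a bound. The other group's mean is then set against the mean of, per array, the higher of its background and the gene's own value. It set 5 arrays (6.75 to 6.85) apart from 9 (6.30 to 6.57); the 5 also had a narrower spread of values (SD 1.75 to 1.80, against 1.80 to 1.89), and 8582 genes differed between the sets when the groups were taken into account. Since each group holds arrays of both sets, results are also given with the split as a block and within the set of 9. Other alternatives were median centring, quantile normalization of the tested rows, a prior with trend and robust fitting, array weights, leaving out the dimmest 25% or 50% of the rows, the mean of all probe sets of a gene, testing every row, only the arrays of the groups compared, a fold minimum of 1.5, the replicate number as a block, and leaving out each array. The alternative with another pseudocount applies only to linear values and was not run.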

Results

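Gene expression was measured in the epididymal fat pad, a visceral fat depot of male mice, with 14 Affymetrix arrays, 1 per animal. The animals were C57BL6/J wild type (WT) or carried the genotype that the labels call EKO and tie to apolipoprotein E. They ate a normal diet or a Western diet, which the labels describe as holding 42% milk fat and name HFD, for 24 weeks from 8 weeks of age. There were 3 WT arrays on normal diet, 3 WT on Western diet, 4 EKO on normal diet and 4 EKO on Western diet. The comparisons ask how the diet changed the tissue in each genotype, how the genotypes differed on each diet, and whether the diet effect depended on genotype (the interaction). Array medians over all rows lay between 7.92 and 8.10 on the log2 scale, and arrays of the same group correlated at 0.976 to 0.995. The number of arrays per group limits the precision. Below, a log2 fold change is followed by ± its standard error and a group level by ± SD. All adjusted p values of single genes come from limma, over 19937 genes.

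Apoe, which encodes the lipoprotein ligand named in the genotype, was far lower in every EKO array. Its level (probe set 10560624) was 13.41 ± 0.24 in WT on normal diet and 13.39 ± 0.26 in WT on Western diet (SD, n = 3 each), against 9.74 ± 0.22 and 10.04 ± 0.19 in EKO (SD, n = 4 each). Apoe fell by 3.67 ± 0.16, adjusted p = 1.32e-08, on normal diet. On Western diet it fell by 3.36 ± 0.16, adjusted p = 4.6e-08. The highest EKO array (10.26) lay below the lowest WT array (13.13). The genotype labels of all 14 arrays thus matched the Apoe level. Diet gave Apoe log2 fold changes of -0.01 ± 0.17, adjusted p = 0.993, in WT and 0.30 ± 0.14, adjusted p = 0.946, in EKO.

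**Figure D1:**
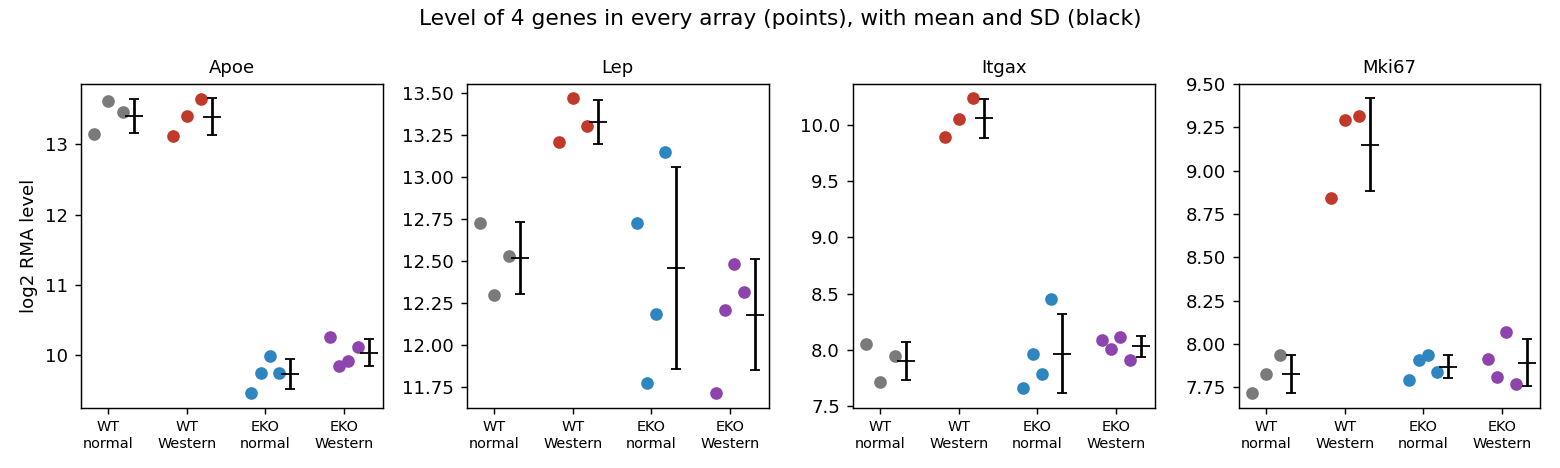
Log2 RMA level (vertical axis) of Apoe, Lep, Itgax and Mki67 in each of the 14 arrays (points), by group (horizontal axis), with the group mean and SD in black. Apoe lies above 13 in every WT array and between 9.46 and 10.26 in the EKO arrays, and the 3 WT arrays on Western diet lie above all other arrays for Itgax and Mki67.

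In WT mice on Western diet 13 of 21 macrophage genes, 12 of 15 genes of dividing cells and 8 of 20 cholesterol synthesis genes rose, and 9 of 13 mesothelial and 6 of 14 insulin signalling genes fell. None of these 5 lists passed with an estimated correlation (adjusted p = 0.128, 0.0853, 0.168, 0.0755 and 0.157). The largest rises were those of Atp6v0d2, a proton pump subunit of macrophages and osteoclasts (log2 fold change 3.71 ± 0.46, adjusted p = 0.000508), Lipf, which encodes gastric lipase (3.65 ± 0.47), and Slc5a7, a choline transporter (3.27 ± 0.48; n = 3 and 3). The kinase gene Cdkl4 rose at least 8.99-fold, since its level on normal diet (6.51 ± 0.28, SD, n = 3) lay at the array background. On the log2 scale Lctl rose by 2.87 ± 0.32, the meiotic gene Sycp3 by 2.51 ± 0.44, and Mmp12, the macrophage elastase, by 2.49 ± 0.48. Gpr50 rose by 2.36 ± 0.33, Prune2 by 2.24 ± 0.35, and Gpnmb, a glycoprotein of lipid-laden macrophages, by 2.24 ± 0.34. In the other direction, Fam13a (-2.59 ± 0.44), the acyl-CoA synthetase gene Acsm3 (-2.48 ± 0.54), Dennd2d (-2.43 ± 0.24) and the adhesion receptor gene Adgrg2 (-2.15 ± 0.17) fell. So did the carboxylesterase gene Ces1f (-1.92 ± 0.30), the angiotensinogen gene Agt (-1.84 ± 0.19) and Tst (-1.65 ± 0.41). The amino acid transporter gene Slc43a1 (-1.58 ± 0.37), the thrombomodulin gene Thbd (-1.57 ± 0.29) and Rnf144b (-1.49 ± 0.20) fell as well. For these 20 genes the WT arrays on both diets did not overlap, and the largest adjusted p was 0.0311, for Tst.

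Of the 21 measured macrophage genes, 13 rose and 1 fell over all genes (19 higher and 1 lower adjusted over the list alone). The macrophage genes had a camera adjusted p = 7.81e-18, and adjusted p = 0.128 with an estimated correlation. Mpeg1, a pore-forming protein of phagocytes, rose from 8.51 ± 0.27 to 10.51 ± 0.18 (SD, n = 3 each). The lysosomal protease gene Ctss rose by 1.79 ± 0.25, while Mertk, a receptor for dying cells, fell by 0.77 ± 0.16. Among 18 genes of lipid-associated macrophages, 12 rose and 1 fell (12 higher and 1 lower adjusted over the list alone). The lipid-associated macrophage genes had a camera adjusted p = 2.89e-14, and adjusted p = 0.0718 with an estimated correlation. Dcstamp, needed for macrophage fusion, rose by 0.54 ± 0.13 and Acp5, an acid phosphatase, fell by 0.51 ± 0.12. None of the 15 resident macrophage genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.529). Of 27 cytokine and chemokine genes 5 rose and none fell (16 higher and 1 lower adjusted over the list alone), with Ccl3 up by 1.35 ± 0.23 and the chemokine receptor gene Ccr2 by 1.30 ± 0.27. The cytokine and chemokine genes had a camera adjusted p = 4.21e-08, and adjusted p = 0.0718 with an estimated correlation. Of 8 MHC class II genes 4 rose (7 higher and 0 lower adjusted over the list alone), among them Cd74, the invariant chain, by 0.77 ± 0.19. The MHC class II genes had a camera adjusted p = 6.86e-07, and adjusted p = 0.157 with an estimated correlation.

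Genes of dividing cells rose in 12 of 15 (14 higher and 0 lower adjusted over the list alone). The proliferation genes had a camera adjusted p = 7.56e-19, and adjusted p = 0.0853 with an estimated correlation. Ccna2, a cyclin, rose by 1.42 ± 0.24 and the division marker Mki67 by 1.32 ± 0.12, from 7.83 ± 0.11 to 9.15 ± 0.27 (SD, n = 3 each). Of 20 genes of cholesterol synthesis and uptake, 8 rose (14 higher and 0 lower adjusted over the list alone), with Lss, lanosterol synthase, up by 1.77 ± 0.32 and Dhcr7, the last enzyme of the pathway, by 1.43 ± 0.24. The cholesterol synthesis and uptake genes had a camera adjusted p = 3.49e-12, and adjusted p = 0.168 with an estimated correlation. Of 17 genes of cholesterol efflux and storage, 5 rose (6 higher and 1 lower adjusted over the list alone), among them the cholesteryl ester hydrolase gene Nceh1 by 1.47 ± 0.22 and Npc2, a lysosomal cholesterol carrier, by 0.81 ± 0.15. The cholesterol efflux and storage genes had a camera adjusted p = 7.79e-05, and adjusted p = 0.128 with an estimated correlation. Lysosomal genes rose in 7 of 20 (10 higher and 0 lower adjusted over the list alone), with Lipa, the lysosomal acid lipase, up by 1.09 ± 0.13. The lysosome genes had a camera adjusted p = 2.14e-10, and adjusted p = 0.168 with an estimated correlation. Extracellular matrix genes rose in 5 of 26 (12 higher and 0 lower adjusted over the list alone), led by the protease inhibitor gene Timp1 at 1.93 ± 0.29. The extracellular matrix genes had a camera adjusted p = 2.69e-08, and adjusted p = 0.202 with an estimated correlation. Saa3, a serum amyloid of macrophages and fat, rose by 2.24 ± 0.32 and was the 1 of 15 acute phase and complement genes to pass (4 higher and 0 lower adjusted over the list alone). The acute phase and complement genes had a camera adjusted p = 0.0101, and adjusted p = 0.184 with an estimated correlation. That list's call ended without WT replicate 2 on normal diet (adjusted p = 0.0593).

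All 13 mesothelial genes had values below 0, and 9 fell (0 higher and 12 lower adjusted over the list alone). The mesothelial genes had a camera adjusted p = 1.49e-13, and adjusted p = 0.0755 with an estimated correlation. The uroplakin genes Upk1b (-1.42 ± 0.21) and Upk3b (-1.17 ± 0.19) fell. So did Wt1, a transcription factor of the mesothelium (-0.87 ± 0.21). Of 14 insulin signalling genes 6 fell (0 higher and 6 lower adjusted over the list alone), among them the insulin-repressed phosphoenolpyruvate carboxykinase gene Pck1 (-1.38 ± 0.22), the receptor substrate gene Irs1 (-1.13 ± 0.22) and the receptor gene Insr (-0.50 ± 0.11). The insulin signalling genes had a camera adjusted p = 0.000341, and adjusted p = 0.157 with an estimated correlation. Because insulin represses Pck1, the direction of this list, in any comparison, does not give a direction of signalling. Of 19 adipocyte genes 4 fell (0 higher and 5 lower adjusted over the list alone), including the adiponectin gene Adipoq (-0.45 ± 0.09) and the glucose transporter gene Slc2a4 (-0.60 ± 0.13). The adipocyte genes had a camera adjusted p = 0.000221, and adjusted p = 0.128 with an estimated correlation. Of 12 smooth muscle and pericyte genes 1 fell (0 higher and 4 lower adjusted over the list alone), the smooth muscle myosin gene Myh11 (-0.78 ± 0.19). The smooth muscle and pericyte genes had a camera adjusted p = 7.79e-05, and adjusted p = 0.168 with an estimated correlation. The epididymis list, which marks the neighbouring organ, had a mean log2 fold change of -0.02 over 15 genes (camera adjusted p = 0.888). Lep, the leptin gene, stood at 12.52 ± 0.21 on normal and 13.33 ± 0.13 on Western diet (SD, n = 3 each) with no overlap, but its log2 fold change of 0.81 ± 0.27, adjusted p = 0.115, did not pass over all genes.

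Over all genes, 1094 of 19937 passed at an adjusted p under 0.05, 636 higher and 458 lower on Western diet, and 698 of them changed at least 1.5-fold. By camera, 12 of the 33 lists were higher and 8 lower, and 0 lists passed with an estimated correlation. By fry, which tests whether a list's genes shift in one direction between the groups compared, 17 lists passed. The arrays also fell into 2 sets by background: 5 arrays, 1 of 3 in each WT group, 1 of 4 in EKO on normal diet and 2 of 4 in EKO on Western diet, had a higher level of olfactory and vomeronasal receptor rows (6.75 to 6.85) than the other 9 (6.30 to 6.57). The 5 were WT replicate 1 on normal diet, WT replicate 1 on Western diet, EKO replicate 2 on normal diet, and EKO replicates 1 and 3 on Western diet. With this split as a block, chosen after the data were seen, 2007 genes passed (1063 higher, 944 lower), and within the 9 arrays of lower background 2152 passed (1322 higher, 830 lower). The 5 others hold 1 WT array per diet, too few for a test; in that pair 87.1% of the 2152 genes had the same sign. Without a single WT array the count ranged from 415 (without WT replicate 3 on Western diet) to 1514 (without WT replicate 1 on Western diet), and it was 527, 528 and 584 without WT replicates 3 and 2 on normal diet and replicate 2 on Western diet; with only the 6 WT arrays it was 479.

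**Figure D2:**
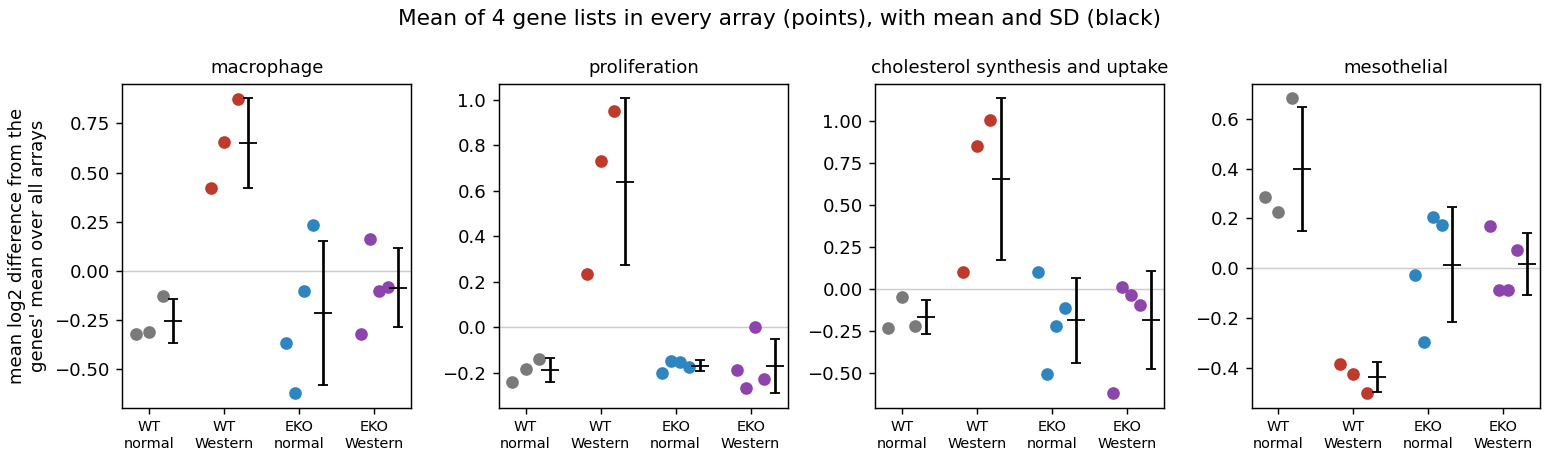
Mean over the genes of 4 lists (macrophage, proliferation, cholesterol synthesis and uptake, mesothelial) in each of the 14 arrays (points), as the log2 difference from each gene's mean over all arrays (vertical axis), by group (horizontal axis), with the group mean and SD in black. The 3 WT arrays on Western diet lie at 0.42 to 0.87 for the macrophage list and at -0.50 to -0.39 for the mesothelial list.

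In EKO mice no gene passed the threshold for the same diet contrast (n = 4 and 4). Itgax, the CD11c gene of inflammatory macrophages, was 7.97 ± 0.35 on normal and 8.03 ± 0.09 on Western diet in EKO, against 7.91 ± 0.17 and 10.06 ± 0.17 in WT. Mki67 was 7.87 ± 0.07 and 7.89 ± 0.14 in EKO, and Lep 12.46 ± 0.60 and 12.18 ± 0.33, a log2 fold change of -0.28 ± 0.24, adjusted p = 0.946. The smallest p values among higher values belonged to the muscle methyltransferase gene Smyd1 (0.85 ± 0.12, adjusted p = 0.112), Dipk2a (0.49 ± 0.10), the sphingomyelin synthase gene Sgms2 (0.42 ± 0.09), Lctl (1.20 ± 0.28) and Cox8b, a respiratory subunit of brown fat and muscle (1.02 ± 0.24). Those among lower values belonged to Rnf144b (-1.02 ± 0.18, adjusted p = 0.323), Alkal2 (-0.95 ± 0.17), Trabd2b (-1.38 ± 0.25), Ccbe1 (-0.60 ± 0.12) and Gnb4 (-0.86 ± 0.17), and none of these 10 passed.

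By camera 3 lists were higher and 3 lower, none with an estimated correlation, and fry called 0. Fatty acid oxidation genes had a mean of 0.15 (0 higher and 0 lower adjusted over the list alone) and cholesterol efflux and storage genes 0.17 (3 higher and 0 lower adjusted over the list alone), where Abcg1, a sterol exporter, was at 0.80 ± 0.21, adjusted p = 0.67. The fatty acid oxidation genes had a camera adjusted p = 0.000278, and adjusted p = 0.761 with an estimated correlation. The cholesterol efflux and storage genes had a camera adjusted p = 0.0165, and adjusted p = 0.735 with an estimated correlation. Neutrophil genes had a mean of 0.11 (2 higher and 0 lower adjusted over the list alone). The neutrophil genes had a camera adjusted p = 0.00127, and adjusted p = 0.735 with an estimated correlation. Smooth muscle and pericyte genes were at -0.31 (0 higher and 1 lower adjusted over the list alone), immediate early and heat shock genes, which respond to handling, at -0.32 (0 higher and 0 lower adjusted over the list alone), and extracellular matrix genes at -0.11 (0 higher and 0 lower adjusted over the list alone). The smooth muscle and pericyte genes had a camera adjusted p = 2.87e-09, and adjusted p = 0.358 with an estimated correlation. The immediate early and heat shock genes had a camera adjusted p = 0.000278, and adjusted p = 0.761 with an estimated correlation. The extracellular matrix genes had a camera adjusted p = 0.00127, and adjusted p = 0.81 with an estimated correlation. Without EKO replicate 2 on Western diet the neutrophil mean was 0.053 (adjusted p = 0.132), and its call ended in 5 of 26 alternatives. The matrix mean was 0.013 (adjusted p = 0.513) without EKO replicate 4 on normal diet, so its sign rests on 1 array, and the call ended in 4 of 26. The call of cholesterol efflux and storage ended in 4 of 26 and that of fatty acid oxidation in 1 of 26, the latter with means of 0.11 to 0.27; the immediate early mean was -0.20 with array weights. The macrophage list had a mean of 0.13 (camera adjusted p = 0.0897) and the proliferation list -0.0014 (camera adjusted p = 0.949). The macrophage list did pass in 10 of 26 alternatives, with the background block at 0.21 (adjusted p = 9.74e-05), and its mean ranged from -0.0075 without EKO replicate 2 to 0.28 without EKO replicate 4 on normal diet. In the arrays of lower background the proliferation list passed at -0.072 (adjusted p = 0.0367). At an unadjusted p under 0.05 there were 883 genes, where 996.85 are expected by chance, and the smallest adjusted p was 0.112. With the background split as a block and within the 9 arrays of lower background, limma again called 0 genes; array weights gave 8, the background level as a covariate 1, the replicate block 1, and leaving out EKO replicate 2 on normal diet or EKO replicate 2 on Western diet 4 and 1. On simulated values with 4 against 4 arrays, the test recovered 94% of genes changed by 1 on the log2 scale. Those values had independent noise per gene and no background split, so that share need not hold for the real arrays. In the real arrays Trabd2b, Lctl, Rnf144b and Cox8b changed by more than 1 in size and did not pass.

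The diet effect differed between the genotypes for 96 genes by the interaction test (n = 14), 67 with a lower and 29 with a higher diet effect in EKO. Of the 67, all 67 had passed as higher on Western diet in WT, with a median diet log2 fold change of 1.34 in WT and 0.01 in EKO; of the 29, 27 had passed as lower in WT, with medians of -1.10 and 0.01. The interaction contrast contains the WT diet contrast, so this overlap is partly built in. The smallest p values were those of Tfr2, a transferrin receptor (-1.98 ± 0.15, adjusted p = 4.53e-05), and Mrc2, an endocytic collagen receptor (-2.03 ± 0.16), followed by Cdkl4 and the kinetochore gene Spc25, and then Itgax (-2.09 ± 0.22, adjusted p = 0.000604), Fam122b (-1.498 ± 0.16), Adgrg2 (1.87 ± 0.23), the interleukin receptor gene Il7r (-2.25 ± 0.28), Mki67 (-1.30 ± 0.16) and Eci3, an enoyl-CoA isomerase (1.34 ± 0.17, adjusted p = 0.00242). Cdkl4 (9.74 in WT on Western diet, 6.51 to 6.77 in the other groups) and Spc25 (7.83, 6.32 to 6.35) had 3 group means within the array background, so no size is given for them. Lep (-1.08 ± 0.36, adjusted p = 0.237) and Apoe (0.31 ± 0.22, adjusted p = 0.685) did not pass.

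By list, the interaction was below 0 for macrophage genes (mean -0.78; 0 of 21 passed over all genes and 0 higher and 16 lower adjusted over the list alone). The macrophage genes had a camera adjusted p = 4.27e-14, and adjusted p = 0.184 with an estimated correlation. For lipid-associated macrophage genes 3 of 18 passed below 0 (1 higher and 11 lower adjusted over the list alone), among them Ctsk, a cathepsin, at -1.54 ± 0.25. The lipid-associated macrophage genes had a camera adjusted p = 7.09e-12, and adjusted p = 0.0882 with an estimated correlation. Of the proliferation genes 2 of 15 passed below 0 (0 higher and 13 lower adjusted over the list alone), and of the cholesterol synthesis genes 0 of 20 (0 higher and 9 lower adjusted over the list alone). The proliferation genes had a camera adjusted p = 9.27e-18, and adjusted p = 0.0999 with an estimated correlation. The cholesterol synthesis and uptake genes had a camera adjusted p = 1.39e-11, and adjusted p = 0.184 with an estimated correlation. The mesothelial list was above 0 (mean 0.84; 0 of 13 over all genes and 11 higher and 0 lower adjusted over the list alone). The mesothelial genes had a camera adjusted p = 3.55e-13, and adjusted p = 0.0882 with an estimated correlation. In the insulin signalling list Pck1 passed above 0 (1.66 ± 0.29; 3 higher and 1 lower adjusted over the list alone). The insulin signalling genes had a camera adjusted p = 0.0213, and adjusted p = 0.328 with an estimated correlation. By camera 6 lists lay above and 14 below 0, of which 0 passed with an estimated correlation and 4 by fry; the insulin signalling call ended in 5 of 25 alternatives and the proliferation call in 1 of 25, with 1 of its 15 genes left. With the background split as a block 320 genes passed (132 higher, 188 lower) and within the arrays of lower background 566 (177 higher, 389 lower). The count without a single array ranged from 37 (WT replicate 2 on normal diet) to 499 (WT replicate 1 on Western diet), and also moved by over 1.5 times, to 45, 40, 38, 57, 148, 62, 61 and 43, without WT replicate 3 on normal diet, WT replicates 2 and 3 on Western diet, EKO replicates 1 and 2 on normal diet, and EKO replicates 1, 2 and 4 on Western diet.

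Across all 19937 genes the diet log2 fold changes of WT and EKO, which share no array, correlated at 0.229 (Pearson) and 0.119 (Spearman); genes are not independent replicates, so no p is given. Pearson's value was 0.088 without WT replicate 1 on Western diet, 0.124 and 0.365 without EKO replicates 2 and 4 on normal diet, and 0.117 in the arrays of lower background. Of the 1094 genes past the threshold in WT, 72.6% had the same sign in EKO. The median of the 636 higher genes was 0.74 in WT and 0.05 in EKO, and that of the 458 lower genes was -0.60 and -0.11. No overlap of calls can be given, since EKO had 0.

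**Figure D3:**
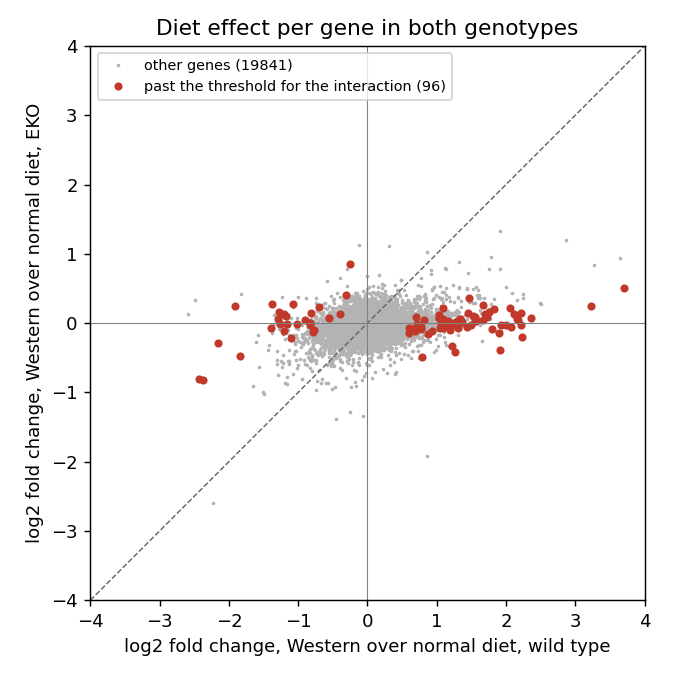
Log2 fold change of Western over normal diet in EKO (vertical axis) against that in WT (horizontal axis) for each of 19937 genes (points), with the 96 genes past the threshold for the interaction in red and equal change as the dashed line. The red points spread along the horizontal axis with a median near 0.01 on the vertical axis.

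On normal diet 1 gene, Apoe, passed between the genotypes (n = 3 and 4). Apod, which encodes another apolipoprotein, had the next smallest p at 1.39 ± 0.20, adjusted p = 0.0568, and did not pass. In 7 of 26 alternatives Apod did pass, and its adjusted p ranged from 0.00361 to 1. The other higher values with the smallest p were those of the small heat shock protein gene Hspb6, which lies within 20 Mb of Apoe (0.72 ± 0.15), the sterol transporter gene Gramd1b (0.46 ± 0.11), Tcim (0.47 ± 0.12) and Klf12 (0.46 ± 0.13), none past the threshold. Nnt, which differs between C57BL/6 substrains, was at 0.11 ± 0.14, adjusted p = 1, and Lep at -0.06 ± 0.26, adjusted p = 1. Mast cell genes were lower as a list (mean -0.29 over 10 genes, 2 of them past adjusted over the list alone and 0 over all genes; camera adjusted p = 5.76e-09, and adjusted p = 0.0219 with an estimated correlation), with the mast cell protease gene Mcpt4 at -0.74 ± 0.21. All 13 mesothelial genes had values below 0 (mean -0.38; 0 higher and 0 lower adjusted over the list alone). The mesothelial genes had a camera adjusted p = 4.15e-19, and adjusted p = 0.0341 with an estimated correlation. Extracellular matrix genes had a mean of -0.12 (0 higher and 0 lower adjusted over the list alone) and MHC class II genes of 0.19 (0 higher and 0 lower adjusted over the list alone). The extracellular matrix genes had a camera adjusted p = 0.000367, and adjusted p = 0.635 with an estimated correlation. The MHC class II genes had a camera adjusted p = 2.85e-05, and adjusted p = 0.535 with an estimated correlation. The mesothelial mean was -0.24 without WT replicate 3 on normal diet. Without EKO replicate 4 on normal diet the MHC class II mean was 0.07 (adjusted p = 0.0609). The matrix mean ranged from -0.24 to -0.039, and its call ended in 3 of 26 alternatives; the mast cell mean was -0.47 over the 4 genes left without the dimmer 50% of the rows.

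By camera 7 lists were higher and 6 lower in EKO, and fry called 0. There were 226 genes at an unadjusted p under 0.05, where 996.85 are expected by chance. A count below chance means that the p values ran high in this contrast, so genes that did not pass cannot be taken as equal between the genotypes. With the background split as a block 2 genes passed, and 2 within the arrays of lower background; without WT replicate 1 on normal diet the count was 3, and without EKO replicate 4 on normal diet 2.

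On Western diet 13 of 21 macrophage, 16 of 26 matrix, 13 of 15 dividing-cell and 9 of 20 cholesterol synthesis genes were lower in EKO than in WT fat, and 4 of 19 adipocyte genes were higher (n = 4 and 3). None of these 5 lists passed with an estimated correlation (adjusted p = 0.2, 0.113, 0.104, 0.2 and 0.104). The log2 fold change of EKO over WT was -3.47 ± 0.43, adjusted p = 0.000432, for Atp6v0d2, -3.23 ± 0.44 for Lipf, -2.89 ± 0.45 for Slc5a7 and -2.45 ± 0.45 for Mmp12. It was -2.30 ± 0.31 for Gpr50, -2.28 ± 0.32 for Gpnmb, -2.27 ± 0.41 for Sycp3 and -2.23 ± 0.33 for Oxtr, the oxytocin receptor gene. Cdkl4 was at least 7.51-fold lower in EKO, where its level (6.77 ± 0.28, SD, n = 4) lay at the array background. Among higher genes it was 2.97 ± 0.50, adjusted p = 0.00341, for Acsm3, 2.73 ± 0.41 for Fam13a, 2.38 ± 0.28 for Ces1f, 2.04 ± 0.16 for Adgrg2 and 1.83 ± 0.22 for Dennd2d. Orm3, an acute phase protein gene, stood at 1.51 ± 0.22, St6galnac5 at 1.495 ± 0.24, Pck1 at 1.48 ± 0.20, Agt at 1.41 ± 0.18 and the glutathione transferase gene Gsta4 at 1.37 ± 0.17. Lep fell by 1.14 ± 0.26, adjusted p = 0.0178, with no overlap between the groups, and passed in 23 of 26 alternatives. The adjusted p of Lep was 0.0860 without WT replicate 2, 0.0840 without WT replicate 3 and 0.0527 without EKO replicate 1 on Western diet, and ranged from 2.25e-05 to 0.0860. Nnt was at 0.14 ± 0.14, adjusted p = 0.637.

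Extracellular matrix genes were lower in EKO in 16 of 26 (0 higher and 23 lower adjusted over the list alone), with Timp1 at -1.92 ± 0.27 and the collagen cross-linking enzyme gene Lox at -1.77 ± 0.23. The extracellular matrix genes had a camera adjusted p = 2.93e-17, and adjusted p = 0.113 with an estimated correlation. Macrophage genes were lower in 13 of 21 (1 higher and 17 lower adjusted over the list alone), with Ctss at -1.59 ± 0.24, and lipid-associated macrophage genes in 11 of 18 (1 higher and 13 lower adjusted over the list alone). The macrophage genes had a camera adjusted p = 1.58e-13, and adjusted p = 0.2 with an estimated correlation. The lipid-associated macrophage genes had a camera adjusted p = 7.44e-13, and adjusted p = 0.104 with an estimated correlation. Of the proliferation genes 13 of 15 were lower (0 higher and 14 lower adjusted over the list alone), and of the cholesterol synthesis genes 9 of 20 (0 higher and 16 lower adjusted over the list alone), with Lss at -1.496 ± 0.30. The proliferation genes had a camera adjusted p = 2.03e-17, and adjusted p = 0.104 with an estimated correlation. The cholesterol synthesis and uptake genes had a camera adjusted p = 7.44e-13, and adjusted p = 0.2 with an estimated correlation. Acute phase and complement genes were lower in 5 of 15 (1 higher and 6 lower adjusted over the list alone): Saa3 stood at -2.09 ± 0.30 and haptoglobin (Hp) at -1.51 ± 0.21. The acute phase and complement genes had a camera adjusted p = 3.57e-05, and adjusted p = 0.104 with an estimated correlation. Cytokine and chemokine genes were lower in 6 of 27 (0 higher and 8 lower adjusted over the list alone), with Ccl7 at -1.68 ± 0.33, and lysosomal genes in 7 of 20 (0 higher and 11 lower adjusted over the list alone). The cytokine and chemokine genes had a camera adjusted p = 1.06e-06, and adjusted p = 0.104 with an estimated correlation. The lysosome genes had a camera adjusted p = 5.23e-10, and adjusted p = 0.2 with an estimated correlation. Adipocyte genes were higher in 4 of 19 (6 higher and 0 lower adjusted over the list alone), including Adipoq at 0.46 ± 0.09; insulin signalling genes were higher in 5 and lower in 1 of 14 (6 higher and 1 lower adjusted over the list alone), and mesothelial genes higher in 2 of 13 (8 higher and 0 lower adjusted over the list alone). The adipocyte genes had a camera adjusted p = 3.73e-05, and adjusted p = 0.104 with an estimated correlation. The insulin signalling genes had a camera adjusted p = 0.00591, and adjusted p = 0.267 with an estimated correlation. The mesothelial genes had a camera adjusted p = 5.45e-06, and adjusted p = 0.2 with an estimated correlation. The insulin signalling call ended without WT replicate 1 on Western diet (adjusted p = 0.111), and the proliferation call without the dimmer 50% of the rows, which left 1 of its 15 genes.

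Over all genes 1134 passed, 326 higher and 808 lower in EKO, and 667 of them changed at least 1.5-fold. By camera 5 lists were higher and 11 lower, while 0 lists passed with an estimated correlation and 13 by fry. The 3 WT arrays on Western diet also make up the WT diet comparison, so the 2 comparisons share their chance values and no overlap between them is given. With the background split as a block 2033 genes passed (734 higher, 1299 lower) and within the arrays of lower background 1616 (519 higher, 1097 lower). Another quantile normalization moved the split from 28.7% higher to 794 higher and 1051 lower. The count was 2108 without WT replicate 1 on Western diet, 430 and 316 without WT replicates 2 and 3 on Western diet, and 727 and 652 without EKO replicates 1 and 4 on Western diet.

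Genes that neighbour Apoe were examined because a gene knocked out in another strain can carry flanking sequence with it. Of 42 measured genes in a list of Apoe neighbours fixed before the data were examined, 0 passed on normal diet and 4 on Western diet, against 1129 of the other genes (Fisher's exact test, two-sided, p = 0.3). Those 4, named by the rule, were lower in EKO: Dmpk at -0.80 ± 0.17, Qpctl at -0.71 ± 0.17, Opa3 at -0.59 ± 0.12 and Mark4 at -0.39 ± 0.10 (0 higher and 4 lower adjusted over the list alone). None of the list passed without WT replicate 2 or WT replicate 3 on Western diet, and 18 passed with array weights. By the gene order of the GRCm38.p6 reference, 551 measured genes lie within 20 Mb on either side of Apoe. The planned test counted genes past the adjusted threshold. On normal diet 0 near genes and 0 others, Apoe aside, passed it. On Western diet 5.81% and 5.70% did (Fisher's exact test, two-sided, p = 0.926). A cutoff outside that plan, an unadjusted p under 0.01, was then used. On normal diet 9 of these 551 (1.63%) lay under it, against 0.15% of the 19303 other genes (Fisher's exact test, two-sided, p = 7.27e-07). With 1 array left out this p lay between 1.95e-07 and 0.00162 (without WT replicate 2 on normal diet), and in the arrays of lower background it was 0.0176. On Western diet the shares were 8.35% and 9.45% (Fisher's exact test, two-sided, p = 0.416). At an unadjusted p under 0.05 on normal diet, the shares were 4.36% of the near genes and 1.04% of the others. With this 20 Mb window neither share exceeds what that threshold gives by chance. Within 5 Mb of Apoe the near share did exceed it, at 7.74% of 155 genes against 1.08% of the others (Fisher's exact test, two-sided, p = 2.09e-07). At an unadjusted p under 0.01 the near shares, 1.94% within 5 Mb and 1.63% within 20 Mb, lay slightly above chance. The contrast on normal diet thus lies partly in the few small p values of the other genes. Fisher's test also counts genes measured on the same arrays as independent. Apoc1, which lies beside Apoe, was at -1.17 ± 0.33, adjusted p = 1, on normal diet. The genotype log2 fold changes on normal and Western diet, which share no array, correlated across genes at 0.0952 (Pearson) and 0.0492 (Spearman). The sign is not settled: Pearson's value was -0.133 and 0.303 without EKO replicates 2 and 4 on normal diet, -0.116 in the arrays of lower background and 0.284 with the replicate block. It was 0.0471, 0.154, 0.0343 and 0.0559 without WT replicates 1, 2 and 3 and EKO replicate 1 on normal diet.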

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

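The tests on the background level, on exchanged diet labels, on a single WT array, on adipocyte share and on epididymal tissue were chosen after the results were seen. The counts over other splits were chosen before. For the genes near Apoe, only the counts past the adjusted threshold were planned before the data were examined. The cutoffs on unadjusted p were not in that plan. The further tests on these genes addressed the pattern that those cutoffs gave, and were chosen before their own results were seen.

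Among the genes named here, single arrays of the EKO groups stood apart from the other 3 of their group by Dixon's test in 14 of 196 gene and group pairs, where chance alone gives about 9.8, or 1 in 20. The values below are log2 levels, that array against the mean of the other 3. EKO replicates 1 and 3 on Western diet and EKO replicate 2 on normal diet were in the set of higher background. EKO replicate 1 on Western diet stood apart for Dmpk (10.69 against 11.15), Hspb6 (11.77 against 11.63), Lctl (9.42 against 9.90), Lss (8.45 against 9.44), Npc2 (10.84 against 11.25) and Scd2 (11.94 against 13.14). EKO replicate 2 on Western diet stood apart for Lipa (11.21 against 11.001). EKO replicate 3 on Western diet stood apart for Mark4 (8.74 against 8.82) and Sdf2l1 (9.17 against 9.34). EKO replicate 4 on Western diet stood apart for Cd3e (8.23 against 8.47). EKO replicate 2 on normal diet stood apart for Gpr50 (7.05 against 6.83) and Thbd (10.84 against 12.03). EKO replicate 4 on normal diet stood apart for Atp6v0d2 (9.02 against 7.16) and Lipf (7.96 against 6.42).

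The diet effect differed between the genotypes for 96 genes. Of the 10 with the smallest p, 8 differed by -1.98 (Tfr2), -2.03 (Mrc2), -2.09 (Itgax), -1.498 (Fam122b), 1.87 (Adgrg2), -2.25 (Il7r), -1.30 (Mki67), 1.34 (Eci3) on the log2 scale, EKO minus WT. The others, Cdkl4 (level 9.74 in WT on Western diet) and Spc25 (level 7.83), have their other 3 group means within the array background, so no size is given. Rows outside the named genes also changed: among 1321 rows with several gene symbols 27 passed for diet in WT and 25 for genotype on Western diet, and among 11799 rows without a symbol 133 and 107 passed, with 3 for the interaction.

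Chance is made unlikely for the genotype contrast on Western diet, but is not excluded. Of the 35 splits of the 7 arrays on Western diet, 1, the real one, gave 1134 genes, and the highest other gave 1. A share of 1 in 35 is the smallest that these splits can reach. The other splits mix the genotypes, which widens the spread that the test uses and lowers their counts. For the interaction, 3 of 100 splits of genotype within diet, the real one included, gave at least its 96 genes; the highest other gave 2499 and the next 2455. Those splits placed arrays of higher background unevenly over the groups compared (3, 0, 0 and 2 arrays in the first, 0, 2, 3 and 0 in the next, counted for EKO Western, EKO normal, WT Western and WT normal), which points to a structure of the arrays, so chance is not called excluded for the interaction although the share is under 0.05; with the background as a block the real split gave 320. The WT diet contrast has 10 splits, too few for a share under 0.05; the real split gave 1094 genes and the highest other 0. For diet in EKO all 35 splits gave at least the 0 genes that limma called for the real one (883 at an unadjusted p under 0.05), and the highest gave 1933, a split that put the 3 EKO arrays of higher background together; with the block the real split still gave 0. For genotype on normal diet 5 of 35 splits gave at least 1 gene, the highest 54, so chance cannot be excluded for the count, although Apoe itself separates the groups.

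For the pattern of most interest, the Western diet response of WT fat that was smaller or absent in EKO fat, an uneven background is argued against for the 96 interaction genes. All 96 passed again with it as a block, among 320, and 86 were among the 566 in the arrays of lower background. The rise from 96 to 320 is not itself support, since the block raised the count for diet in WT as well (1094 to 2007). An exchange of diet labels among EKO arrays that responded as WT did is also argued against. Over the 1094 genes no EKO array lay further than 26.1% of the way from WT on normal to WT on Western diet. The lowest WT array on Western diet lay at 80.6%, though the genes were chosen on the WT arrays. Exchanged labels with a smaller EKO response cannot be judged. EKO replicate 4 on normal diet lay at 21.8%, above EKO replicates 1, 2 and 4 on Western diet (11.2%, 18.9% and 12.3%). The other EKO arrays on normal diet lay at -5.3% to 3.2%. A single deviant WT array is argued against too: for each of 9 pairs of a WT array on either diet, the genes called without the pair had the same sign in it in 82.4% to 100% of cases, although in pairs with WT replicate 1 on Western diet the rises were smaller (median 0.32 to 0.37 against 0.86 to 0.90 in the other arrays). Fewer adipocytes with all other cell types raised alike is argued against, since the macrophage list moved by 0.90 and the mesothelial list by -0.84. A change in adipocyte share along with other changes in cell types stays open, and the adipocyte list fell by 0.20 in the mean. Epididymal tissue in the sample is argued against by a mean of -0.025 for its list, most of whose 15 genes lay among the dimmest 25% of the rows. A candidate explanation is that EKO mice gained less fat on this diet, with less macrophage entry; body and fat pad weights were not analysed here, so this stays untested, as do EKO mice labelled Western that did not eat that diet, and unlabelled processing days.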

How the results depend on the processing

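The alternatives that use the background of the arrays were chosen after the data were seen; the others were chosen before. Counts are of genes past the threshold unless lists are named, and the cause of each change was not tested except where fewer arrays or genes explain it. For diet in WT the count of 1094 became 698 with a fold minimum of 1.5, 1735 with quantile normalization again, 5224 with array weights and 479 with only the 6 WT arrays. It became 2007 with the background block, 2075 with the background covariate and 2152 in the arrays of lower background; all 1094 genes were among the 2007 and 1011 among the 2152. For diet in EKO the 0 of limma (883 at an unadjusted p under 0.05) became 8 with array weights, 1 with the replicate block and 1 with the background covariate. For genotype on normal diet 1 became 2 with trend and robust fitting, array weights, either filter on dim rows, the replicate block, the background block and the arrays of lower background. For genotype on Western diet 1134 became 667 with the fold minimum, 1845 with quantile normalization, 6789 with array weights, 2033 with the background block and 1981 with its covariate. For the interaction 96 became 56 when every row was tested, 285 with quantile normalization, 2338 with array weights, 320 with the background block, 341 with its covariate and 566 in the arrays of lower background. Array weights ranged from 0.296 to 6.84.

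Leaving out each array in turn gave 415 to 1514 genes for diet in WT, 0 to 4 for diet in EKO, 1 to 3 for genotype on normal diet, 316 to 2108 for genotype on Western diet and 37 to 499 for the interaction. The lists past the threshold then numbered 4 to 13 for diet in EKO, with 12, 13 and 10 without EKO replicate 4 on normal diet and EKO replicates 1 and 3 on Western diet, and 8 (without WT replicate 1 on normal diet) to 19 for genotype on normal diet. With an estimated correlation, 0 lists passed for diet in WT, diet in EKO, genotype on Western diet and the interaction, and 2 for genotype on normal diet, where camera with the preset correlation had called 20, 6, 16, 20 and 13. Fry called 17 lists for diet in WT and 13 for genotype on Western diet, 0 for diet in EKO and for genotype on normal diet, and 4 for the interaction. In the arrays of lower background 10 lists passed for diet in EKO.

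For some lists the direction that camera gave turned, which the mean did not always follow. Without the dimmer 50% of the rows 1 of 12 neutrophil genes was left, Mmp9, at -0.54 for diet in EKO. In the arrays of lower background the means for diet in EKO were 0.17 for lipogenesis (-0.060 with all arrays) and 0.12 for oxidative phosphorylation (-0.0043), which changed sign, and -0.072 for proliferation (-0.0014), which did not. For genotype on normal diet the resident macrophage mean was -0.028 in those arrays (-0.18), also with no change of sign. With an array left out the immediate early mean for diet in WT lay between -0.54 and 0.10. For diet in EKO the resident macrophage mean lay between -0.17 and 0.13, lipogenesis between -0.19 and 0.13 and oxidative phosphorylation between -0.068 and 0.085. For genotype on normal diet the macrophage mean lay between -0.11 and 0.18, resident macrophage between -0.30 and 0.0011, fatty acid oxidation between -0.15 and 0.071 and immediate early between -0.46 and 0.17. The matrix mean for diet in EKO turned to 0.013 without EKO replicate 4 on normal diet. Of the calls of named genes, 2159 of 2235 values under other settings kept direction and call and 76 lost the call; with an array left out these were 2248 and 440 of 2688. Of the list calls 831 of 1030 were kept, 197 lost and 2 changed direction, and 960, 87 and 3 of 1050 with an array left out.

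With the replicate number as a block (replicate block) 1300, 1, 2, 1672 and 159 genes passed for diet in WT, diet in EKO, genotype on normal diet, genotype on Western diet and the interaction. The numbers were not taken to pair the arrays, since not every pair of the same number correlated above 0.1 in the deviations from the group means: 12 of 19 did (-0.59 to 0.64), all 6 pairs of replicate 1 among them. Replicate 1 of both WT groups and of EKO on Western diet had higher background. Pairs among these arrays therefore cannot tell a shared number from a shared background level. The median was 0.20 for the same number and -0.095 for other numbers, and 5 of 14 arrays correlated best with an array of their own number. Median centring moved no array by more than 0.04. The alternative with a pseudocount of 16 was not run, since the values are log2. Signal over background limits dim genes, and the highest array mean of the background rows was 6.85.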

Other observations

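The further tests on genes near Apoe were chosen before their own results were seen, but after the cutoffs on unadjusted p had given the pattern. The 3 genes singled out among them were chosen afterwards. Several further lists passed by camera for diet in WT. Of 20 T and NK cell genes 2 rose (3 higher and 0 lower adjusted over the list alone): Il2rb, an interleukin receptor subunit, by 0.56 ± 0.15 and the T cell receptor gene Cd3e by 0.40 ± 0.11. The T and NK cell genes had a camera adjusted p = 7.79e-05, and adjusted p = 0.168 with an estimated correlation. No gene of the interferon response list passed over all genes (mean 0.20 over 16; 1 higher and 0 lower adjusted over the list alone). The interferon response genes had a camera adjusted p = 0.00237, and adjusted p = 0.385 with an estimated correlation. Mast cell genes had a mean of -0.27 over 10 (0 higher and 0 lower adjusted over the list alone) and endothelial genes of -0.18 over 15 (0 higher and 0 lower adjusted over the list alone). The mast cell genes had a camera adjusted p = 0.0127, and adjusted p = 0.168 with an estimated correlation. The endothelial genes had a camera adjusted p = 0.0127, and adjusted p = 0.462 with an estimated correlation. Oxidative phosphorylation and citrate cycle genes had a mean of -0.15 over 27, none past over all genes (0 higher and 0 lower adjusted over the list alone). The oxidative phosphorylation and citrate cycle genes had a camera adjusted p = 0.0127, and adjusted p = 0.703 with an estimated correlation. In the immediate early and heat shock list Atf3, a stress transcription factor, rose by 1.23 ± 0.23 while the chaperone gene Hspa1a fell by 0.52 ± 0.13 (1 higher and 1 lower adjusted over the list alone), and without WT replicate 2 on normal diet the list mean turned to 0.10. The immediate early and heat shock genes had a camera adjusted p = 0.0322, and adjusted p = 0.612 with an estimated correlation. Without that array the oxidative phosphorylation mean was -0.0043 (adjusted p = 0.879). Calls ended in 4 of 26 alternatives for oxidative phosphorylation, 9 of 26 for immediate early, 2 of 26 for endothelial and 2 of 26 for T and NK cell genes. The T and NK cell mean was 0.13 with array weights, against 0.23. The endothelial and interferon means were -0.096 and 0.11 without WT replicate 3 on Western diet, and the mast cell mean was -0.46 over the 4 genes left without the dimmer 50% of the rows.

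Other lists did not pass by camera for diet in WT but held genes that did. In the thermogenic list the proton channel gene Otop1 rose by 1.53 ± 0.15 and Ebf2, a transcription factor of brown fat precursors, fell by 0.84 ± 0.15; the interaction for Otop1 was -1.43 ± 0.20, adjusted p = 0.0053. In the unfolded protein response list Sdf2l1 rose by 0.78 ± 0.14 and Asns, asparagine synthetase, fell by 0.83 ± 0.11, and Asns was at 1.06 ± 0.10, adjusted p = 4.62e-05, for EKO over WT on Western diet. In the lipogenesis list the desaturase gene Scd2 rose by 1.91 ± 0.36 and the glucose-sensing factor gene Mlxipl fell by 0.80 ± 0.20. In the neutrophil list S100a8 rose by 0.57 ± 0.14 and Mmp9 fell by 1.31 ± 0.22.

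The genes near Apoe give a hypothesis. Among the 9 with an unadjusted p under 0.01 on normal diet, C5ar2 (log2 fold change -0.32 on normal and -0.66 on Western diet), Ap2s1 (-0.40 and -0.64) and Lilra5 (0.31 and 0.38) also passed on Western diet. They were singled out after their values were seen. The rest of the 9 did not pass there. Lgals7, with the smallest p on normal diet, went from -0.71 to -0.10, and Sbsn changed sign (-0.46 and 0.15). Apoc1 (-1.17 and -0.68), Hspb6 (0.72 and 0.33), Lgals4 (-0.68 and -0.29) and Blvrb (0.46 and 0.26) kept their sign with smaller values. Other runs of 551 neighbouring genes did not hold as many as the 9: 0% of 8371 overlapping runs elsewhere did (highest 3). Neighbouring runs share almost all of their genes, so the 8371 are not separate trials. Background does not account for the 9, since Fisher's exact p was 2.68e-05 with it as a block, though 0.0176 in the arrays of lower background alone. Sequence of another strain around Apoe is a candidate explanation: of the 24 near genes with an unadjusted p under 0.05 on normal diet, 83.3% had the same sign on Western diet, in other arrays, against a median of 50% and a 95th percentile of 62.5% in 1000 random sets of the other 201 genes. Whether such sequence would change the RNA or only how it binds the probes was not tested, and effects of the loss of Apoe on its neighbours stay open.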
